A study of Homo sapiens with 30 samples.

How the data were processed

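The series is a SLAM-seq experiment in 22Rv1 cells, a human line of castration-resistant prostate cancer. SLAM-seq marks new RNA: cells take up 4-thiouridine (s4U), iodoacetamide alkylates it in the extracted RNA, and reads of that RNA carry T-to-C conversions. Per the labels' protocols, cells received 800 µM s4U for 30 min, and the 0 h libraries were collected then. The medium was then replaced by medium with 800 µM s4U and DMSO, 1.2 µM KB742 or 4 µM KI-ARv-03, and cells were collected 2, 4 or 8 h later. Libraries read the 3′ ends of transcripts. The 30 libraries form 10 groups of 3. Nothing in the labels says that replicates came from separate cultures, so the 3 libraries of a group may be technical replicates.

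The labels conflict in places. For 8 of the 9 samples titled 4 h the treatment field names another time, and the time in the title was used. A treatment field for KB742 reads as a dose above the protocol's 1.2 µM, and the protocol's dose was used. The treatment protocol and the descriptions name DMSO for every sample, so the compound was taken from the titles.

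The deposited table has 85618 rows of RefSeq transcripts on hg19, per the submitters' processing notes, of which 49163 are messenger RNAs and 36455 non-coding RNAs. The unit of the first measure is a signal, headed CPM in the deposited table: reads scaled to a common library total. A library's values sum to 0.84 to 1.38 times that total. Reads shared by overlapping transcripts could give sums above the total but not those below it, and the cause was not tested. Every value above 0 was a whole multiple of a library's smallest step (100% of values within 0.05 of a whole number), and whole reads were recovered on that basis. The unit of the second measure is a fraction, headed conversion in the deposited table. Its numerator and denominator are not in the table, so it is given here as the conversion level in percent and not as a share of reads. The aligner, the conversion caller and their settings are not given in the sources used here.

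A gene was represented by its transcript with the most reads over all libraries. Of 50925 distinct RefSeq identifiers, 50153 (98.5%) matched a gene symbol, and transcripts without any name held 0.291% of reads. That gave 22383 genes, of which 17184 had a read. The libraries held 3376884 to 9265131 reads behind the CPM values, 1416051 to 3971411 of them on the genes kept. With these depths and 3 libraries per group, the 95% interval of a log2 difference had a median half-width of 0.865. Intervals cover the spread between libraries only, since reads carry no molecular identifiers in the table.

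Levels were tested with limma 3.58.1 (trended variances, R 4.3.3). Recovered reads were rescaled by edgeR 4.0.16 TMM factors and turned into log2(CPM + 1). Genes passed filterByExpr with a minimum count of 10, which left 11425. All 30 libraries entered 1 fit of 10 groups. Levels in the text are these rescaled CPM, as mean ± SD of 3 libraries, and changes are log2 differences ± SE. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Conversion was tested with limma on the arcsine of its square root, with the variance trend taken over read depth. A conversion value behind fewer than 20 reads was treated as missing, and a gene was tested where each group had at least 2 values. The text gives conversion as mean ± SD in percent of 3 libraries unless it gives another n. The read-weighted mean conversion of a library was compared between groups with an exact two-sided permutation test, for which 3 libraries against 3 allow no p below 0.1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

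Each compound was compared with DMSO and with the other compound at 2, 4 and 8 h, DMSO at each time was compared with 0 h, and the effect of each compound at 8 h was compared with its effect at 2 h as an interaction. The groups, the comparisons, the scaling, the filter, the gene lists, the list tests and the rule for naming genes were chosen before the data were examined. The choice of edgeR for read counts was replaced by limma, since the table holds no read counts as such. The conversion test, the use of mean conversion and 12 of the alternatives were chosen after the contents of the table were known.

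The 22 gene lists included luminal prostate transcription factors, immediate early and short-lived regulators, anti-apoptotic genes, P-TEFb and RNA polymerase II elongation genes, MYC-activated genes, p53-activated genes, DNA repair genes, heat shock genes, integrated stress and unfolded protein response genes, G2/M genes, S-phase genes, histone genes, ribosomal protein genes, respiratory chain genes of the nucleus, mitochondrially encoded genes, glycolysis and housekeeping genes, interferon-stimulated genes, NF-kB-activated genes, sterol and lipid synthesis genes, neuroendocrine markers, and markers of basal, stromal, endothelial and immune cells. They were tested with limma camera at a preset correlation, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. Mitochondrially encoded genes had 0 members in the table and were not analysed here.

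The named genes followed 3 rules. The first names genes fixed in advance, among them MYC, MCL1, KLK3, TMPRSS2, FKBP5, XIAP, CDK9, HEXIM1 and POLR2A, in the comparisons of a compound with DMSO. The second allows up to 4 members per list with the smallest adjusted p. The third allows up to 8 rises and 8 falls with the largest change among called genes with a mean of at least 10 CPM whose groups do not overlap. A gene outside these rules is named as chosen after its values were seen. Some genes and 1 list are not reported here.

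Changes were simulated in the 2 h libraries of KB742 and DMSO. For levels 200 genes were changed, 2-fold or 4-fold. The test found 5% of those changed 2-fold and 63% of those changed 4-fold, with 0 false calls. For conversion 136 changed genes were tested. The test found 40% of those changed 2-fold and 77.3% of those changed 4-fold, with 7 false calls. The simulated conversion had the same base level in all genes and counting error only. Its shares therefore do not describe the test under the real spread between libraries.

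The alternatives were DESeq2 1.42.0, edgeR's quasi-likelihood test on recovered reads, scaling by library size alone or as deposited, no filter, a 2-fold minimum, another pseudocount, the sum of a gene's transcripts, fits of the compared groups alone, replicate numbers as blocks, at least 50 reads for conversion, conversion on a log2 scale, the median over genes for mean conversion, mean conversion without ribosomal protein genes, leaving out each library in turn, and leaving out 3 libraries that stand apart. ERCC spike-in RNA was added per the labels' protocols, but the table has 0 spike-in rows and no counts of converted reads. The planned scaling by spike-ins, the spike-in share of reads and the tests of converted reads were therefore not run.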

Results

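RNA of 22Rv1 cells, a line of castration-resistant prostate cancer, was measured while CDK9 was inhibited. CDK9 is the kinase of P-TEFb, which releases paused RNA polymerase II into elongation. KB742 and KI-ARv-03 are the CDK9 inhibitors, given at different doses (1.2 and 4 µM), so differences between them are of a compound at its dose. There were 3 libraries at 0 h and 3 for each of DMSO, KB742 and KI-ARv-03 at 2, 4 and 8 h, 30 in all. Every gene tested has a level, in rescaled CPM. It is relative to the other genes of a library, so rises and falls of level are not changes in RNA per cell. Genes with enough reads also have a conversion level, which grows as labelled RNA replaces older RNA. The libraries held 3376884 to 9265131 reads, with 11684 to 14360 genes detected in each.

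How much new RNA did the cells make, and did the inhibitors change it? Mean conversion over all reads was 0.345% ± 0.0600 (SD, n = 3) at 0 h. With DMSO it was 0.792% ± 0.123 at 2 h, 1.08% ± 0.0664 at 4 h and 1.23% ± 0.302 at 8 h. With KB742 it was 0.430% ± 0.0764, 0.412% ± 0.0986 and 0.395% ± 0.0382. That is 0.544, 0.381 and 0.322 of the DMSO value. With KI-ARv-03 it was 0.396% ± 0.0220, 0.661% ± 0.450 and 0.343% ± 0.0630. That is 0.50, 0.611 and 0.280 of the DMSO value. In the exact two-sided permutation test, p was 0.1 (adjusted over 12 comparisons, 0.15) for each compound at each time and for each time with DMSO against 0 h, except KI-ARv-03 at 4 h (exact p = 0.4, adjusted 0.48). The smallest p this design allows is 0.1. The spread of KI-ARv-03 at 4 h came from replicate 1 at 1.18%, against 0.382% and 0.422% in the others, and without it the difference from DMSO went from -0.421 to -0.681 percentage points. The compounds differed from each other by 0.0343, -0.249 and 0.0516 percentage points (KB742 minus KI-ARv-03; exact permutation p = 0.6, 0.6 and 0.3, adjusted 0.6, 0.6 and 0.4). The sign of that difference turned at 2 h without KB742 replicate 1 (-0.00467) and at 4 h without KI-ARv-03 replicate 1 (0.0103). At 2 h it was 0.0218 without KI-ARv-03 replicate 2 and 0.0716 without KB742 replicate 2, and at 4 h -0.388 without KI-ARv-03 replicate 2. At 8 h it was 0.0873 and 0.0276 without KI-ARv-03 replicates 1 and 2 and 0.0319 without KB742 replicate 3. With the median over genes in place of the mean, the compounds differed by -0.0290, -0.422 and 0.0143, so the sign turned at 2 h. The differences from DMSO were then -0.215 and -0.445 with KB742 at 2 and 4 h, and -0.186 and -0.0227 with KI-ARv-03 (-0.361, -0.670, -0.396 and -0.421 with the mean).

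**Figure D1:**
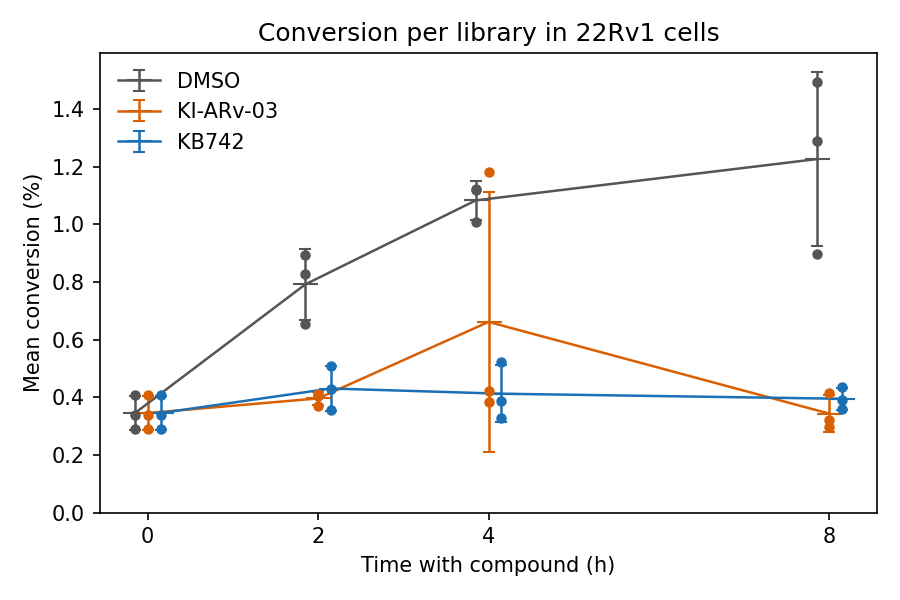
Read-weighted mean conversion of each library in percent (vertical axis) against hours after compound or DMSO was added (horizontal axis), with points for libraries and mean ± SD per group, n = 3. DMSO goes from 0.792% at 2 h to 1.23% at 8 h, while KB742 ends at 0.395% and KI-ARv-03 at 0.343%, near the 0.345% of 0 h.

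The libraries with DMSO show how RNA levels differed from 0 h without an inhibitor. The 0 h libraries were collected before the medium was replaced, so time, the new medium, DMSO and longer s4U cannot be told apart. RGS2, a brake on G-protein signalling, fell from 677 ± 45.2 CPM at 0 h to 25.5 ± 9.33 at 2 h (log2 change -4.75 ± 0.31, adjusted p = 7.12e-11). At 8 h it was at 8.06 ± 3.45 CPM (-6.29 ± 0.31, adjusted p = 3.27e-14). ID3, which blocks DNA binding of helix-loop-helix factors, fell from 332 ± 30.1 to 7.72 ± 3.49 CPM (-5.35 ± 0.39, adjusted p = 1.60e-10). FOXA1, a pioneer transcription factor, fell from 217 ± 42.3 to 25.4 ± 3.88 CPM at 8 h (-3.04 ± 0.35, adjusted p = 2.38e-07). MCL1, a short-lived inhibitor of apoptosis, fell from 187 ± 48.5 to 33.1 ± 12.9 (-2.50 ± 0.40, adjusted p = 1.82e-05). TBX3, a T-box repressor, fell from 269.6 ± 51.0 to 18.2 ± 1.70 CPM at 4 h (-3.80 ± 0.24, adjusted p = 1.44e-11). The ribosomal protein gene RPL19 rose from 1216 ± 317 to 2872 ± 359 and 4665 ± 866 CPM at 4 and 8 h (1.96 ± 0.24, adjusted p = 5.38e-07, at 8 h). UQCR11 of respiratory complex III rose from 264 ± 27.1 to 1010.0 ± 135 (1.93 ± 0.20, adjusted p = 6.34e-08).

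Over all 11425 genes, 10 rose and 302 fell at 2 h with DMSO against 0 h, 653 rose and 1664 fell at 4 h, and 2281 rose and 3319 fell at 8 h. At 2 h the count of 312 went to 187 and 146 without replicates 1 and 2 of 0 h, and to 180 and 140 without replicates 1 and 3 of DMSO. It went to 484 with DESeq2, to 167 in a fit of the 2 groups alone, to 726 on the deposited scaling and to 78 with a pseudocount of 0.25. The 10 rises were 17 and 4 without replicates 1 and 3 of 0 h, and 4, 4 and 2 without replicates 1, 2 and 3 of DMSO. At 4 h the 653 rises went to 244 without 0 h replicate 3 and to 434, 404 and 308 without DMSO replicates 1, 2 and 3. They were 325 with a 2-fold minimum and 282 without the 3 libraries that stand apart. Scaling by library size moved the median of all genes by -0.757 at 8 h, -0.351 at 4 h and -0.125 at 2 h, and the deposited scaling moved it by -0.657, -0.404 and -0.157. Of the genes called, 8.1% were higher at 8 h than at 0 h with either of them, against 40.7% with TMM, and at 4 h 4.5% and 2.4% against 28.2%.

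By function, the lists moved in opposite directions. At 8 h with DMSO, 64 of 71 ribosomal protein genes and 37 of 40 respiratory chain genes were called, all higher than at 0 h, with list medians of 1.65 and 1.75 log2 (0.843 and 0.947 scaled by library size, 0.897 and 1.00 as deposited). Their median conversion was then 0.263% and 0.280%, from 0.104% and 0.095% at 0 h, and that of immediate early genes 33.8%. Their rise went with low conversion, and relative levels do not tell more of this RNA from less of other RNA. Short-lived regulators went the other way: 16 of 23 immediate early genes fell and 2 rose (median -2.10). In all 10 of 15 luminal prostate transcription factors fell (median -2.28), and 17 of 22 G2/M genes fell and 1 rose (median -1.42; -2.21 scaled by library size and -2.01 as deposited). Of the elongation genes, 18 of 28 fell and 2 rose. Of 21 p53-activated genes 11 fell and 2 rose, and of 8 anti-apoptotic genes 6 fell and 1 rose. Of 19 glycolysis and housekeeping genes 13 rose and 3 fell. For the others the counts of rises and falls were 7 and 12 of 32 MYC-activated genes, 1 and 4 of 14 DNA repair genes, 4 and 5 of 17 heat shock genes, 2 and 9 of 19 integrated stress and unfolded protein response genes. They were 3 and 6 of 21 S-phase genes, 4 and 2 of 12 histone genes, 0 and 2 of 6 NF-kB-activated genes, and 6 and 4 of 19 sterol and lipid synthesis genes. Adjusted over the list alone, 65 ribosomal protein, 14 glycolysis, 9 MYC-activated, 7 sterol and 3 p53-activated genes rose, and 11 luminal, 19 elongation and 6 heat shock genes fell, and the other counts given here were equal. Scaled by library size and as deposited, the histone median turned from 0.57 to -0.20 and -0.15. That of S-phase genes went from -0.02 to -0.81 and -0.74, and that of glycolysis and housekeeping genes from 1.35 to 0.55 and 0.61. The sterol genes had a median of 0.09 (-0.706 scaled by library size and -0.635 as deposited) and a mean of -0.26. In the camera test at 8 h the adjusted p was 2.61e-19 for ribosomal protein genes, 1.31e-18 for respiratory chain genes, 2.12e-05 for luminal factors, 2.79e-05 for G2/M genes and 0.000143 for immediate early genes. It was 0.000321 for glycolysis and housekeeping genes and 0.000348 for P-TEFb and elongation genes. Those calls hold with an estimated correlation, and that for p53-activated genes (0.0234) does not (adjusted p = 0.0776 with an estimated correlation). At 2 h immediate early genes (7 of 23 fell, 12 adjusted over the list alone; camera adjusted p = 2.49e-11) were already lower than other genes. So were luminal factors (3 of 15 fell, 7 adjusted over the list alone; adjusted p = 1.91e-05), and both calls hold with an estimated correlation (0.00197 and 0.0139).

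With DMSO, conversion rose with time for most called genes. KLF6, a zinc-finger regulator of the immediate early list, went from 8.74% ± 1.31 to 34.5% ± 1.62 at 2 h and 51.1% ± 1.25 at 8 h with DMSO (adjusted p = 1.43e-07 and 9.32e-14). METTL18, a histidine methyltransferase of a ribosomal protein, went from 7.63% ± 9.09 to 56.5% ± 7.04 (adjusted p = 2.25e-07). SOX4, a developmental factor, went from 1.74% ± 0.481 to 31.7% ± 2.54 (adjusted p = 4.48e-16), and MCL1 from 0.535% ± 0.0722 to 19.8% ± 3.58 (adjusted p = 2.00e-12). The glycolytic transcript GAPDH reached 1.70% ± 0.533 at 8 h from 0.156% ± 0.0416 (adjusted p = 3.33e-10). Conversion rose for 696, 2725 and 2785 genes at 2, 4 and 8 h and fell for 3, 2 and 3, of 8320, 7830 and 6479 tested. All 10, 11 and 10 immediate early genes with values rose, also adjusted over the list alone. The falls were COXFA4L2, RPL10A and TPMT at 2 h (adjusted p = 0.0232, 0.0282 and 0.0463), TAF2 and THOC6 at 4 h (0.0422 and 0.0332) and HBS1L at 8 h (0.00212). NDUFS1 and SNAP25 at 8 h (0.0282 and 0.0436) were named after their values were seen. Without 0 h replicate 3 the call was lost for RPL10A (adjusted p = 0.285), TPMT (0.443), TAF2 (0.364), HBS1L (0.0531), NDUFS1 (0.318) and SNAP25 (0.828). Without DMSO replicate 1 it was lost for TPMT (0.0770), TAF2 (0.0821), NDUFS1 (0.0507) and SNAP25 (0.0696), and without replicate 2 for COXFA4L2 (0.0583), RPL10A (0.0964), TPMT (0.106), TAF2 (0.0799) and SNAP25 (0.0902). Without DMSO replicate 3 it was lost for COXFA4L2 (0.0620), RPL10A (0.108), TPMT (0.116), TAF2 (0.0913), NDUFS1 (0.123) and SNAP25 (0.0819). With replicate blocks it was lost for TAF2 (0.0516) and THOC6 (0.0605), on a log2 scale for TPMT (0.0760), TAF2 (0.0661) and SNAP25 (0.0641), and with at least 50 reads for TAF2 (0.0697). In fits of the 2 groups alone it was lost for COXFA4L2 (0.153), RPL10A (0.120), TPMT (0.187), TAF2 (0.108), THOC6 (0.0733), HBS1L (0.0587), NDUFS1 (0.149) and SNAP25 (0.304). Without the 3 libraries that stand apart it was lost for RPL10A (0.184), TPMT (0.289), TAF2 (0.198), NDUFS1 (0.175) and SNAP25 (0.790). In the camera test ribosomal protein genes ranked below other genes at 8 h (adjusted p = 0.00737, adjusted p = 0.869 with an estimated correlation), although their median conversion rose. The direction was the same, without a call, for DNA repair, heat shock and respiratory chain genes (adjusted p = 0.515, 0.935 and 0.530). At 2 h the total of 699 went to 290 without 0 h replicate 3, to 388 and 364 without DMSO replicates 2 and 3, and to 382 without the 3 libraries that stand apart. At 8 h the total of 2788 went to 1819 without DMSO replicate 2 and to 1841 with at least 50 reads.

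The comparisons of a compound with DMSO ask which transcripts the CDK9 inhibitors changed. At 2 h METTL18 had 2.90 ± 1.19 CPM with KB742 and 2.56 ± 0.654 with KI-ARv-03, against 18.3 ± 4.37 with DMSO (log2 -2.33 ± 0.39, adjusted p = 0.0146, and -2.42 ± 0.39, adjusted p = 0.00955). MIR22HG, the host of a microRNA, was lower with KB742 (7.28 ± 3.05 against 37.8 ± 8.19 CPM, -2.28 ± 0.36, adjusted p = 0.0107). KLF6 was lower with KI-ARv-03 (17.5 ± 5.29 against 78.1 ± 21 CPM, -2.10 ± 0.35, adjusted p = 0.00955). FGF18, a growth factor gene named after its values were seen, was lower with both (-2.60 ± 0.47, adjusted p = 0.0315, and -2.87 ± 0.47, adjusted p = 0.00955). These were the 3 genes called lower with each compound, with 0 called higher by limma (360 and 344 genes at an unadjusted p under 0.05; edgeR called 2 and 3, DESeq2 3 and 7). The FGF18 call with KB742 was lost with DESeq2 (adjusted p = 0.0516), with edgeR (0.335) and with a pseudocount of 0.25 (0.260). The calls rest on single libraries, and the deposited scaling moved the median of all genes by -0.159 with KB742. Without the 3 libraries that stand apart, the differences with KB742 were -2.06 for METTL18, -1.95 for MIR22HG and -2.34 for FGF18, none of them called. With KB742 0 were called without DMSO replicate 1, DMSO replicate 2 or KB742 replicate 2 and 1 without DMSO replicate 3 or KB742 replicate 1. With KI-ARv-03 0 were called without replicates 2 or 3 of DMSO or replicates 1 or 3 of the compound. In a fit of the compared groups alone 0 were called with either compound, METTL18 having adjusted p = 1 with KB742 and 0.0816 with KI-ARv-03.

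Conversion at 2 h was already lower with the inhibitors. ONECUT2, a transcription factor of the luminal list, reached 2.19% ± 0.903 with KB742 and 2.46% ± 0.255 with KI-ARv-03, against 6.34% ± 1.37 with DMSO (adjusted p = 0.000273 and 0.00134). With KI-ARv-03, SOX4 reached 6.21% ± 1.32 against 14.6% ± 2.76 (adjusted p = 0.00240). RSRP1, an arginine- and serine-rich protein gene, reached 5.28% ± 2.25 against 26.5% ± 8.36 (adjusted p = 0.00206). IFI35, an interferon-stimulated gene, reached 0.50% ± 0.707 (n = 2) against 13.7% ± 6.61 (adjusted p = 0.00337). In all, 78 of 8095 genes were lower with KB742 and 65 of 8170 with KI-ARv-03, and 0 were higher with either in limma (1175 and 1105 genes at an unadjusted p under 0.05; no other tool was run on conversion). The 78 went to 29 and 11 without DMSO replicates 2 and 3, and to 17 and 40 without KB742 replicates 2 and 3. It was 37 without the 3 libraries that stand apart and 0 in a fit of the 2 groups alone (ONECUT2 adjusted p = 0.197). The 65 went to 34 and 19 without DMSO replicates 2 and 3, and to 32, 22 and 36 without KI-ARv-03 replicates 1, 2 and 3. It was 32 in a fit of the 2 groups alone, 105 with at least 50 reads and 256 without the 3 libraries that stand apart. In that fit of 2 groups ONECUT2 (adjusted p = 0.0560), SOX4 (0.0658), RSRP1 (0.0660) and IFI35 (0.0867) lost their calls.

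At 4 h METTL18 had 3.0 ± 1.61 CPM with KB742 and 2.67 ± 0.324 with KI-ARv-03, against 23.5 ± 1.75 with DMSO (-2.68 ± 0.39, adjusted p = 0.00145, and -2.74 ± 0.39, adjusted p = 0.000660). MIR22HG had 8.81 ± 3.07 and 7.79 ± 1.86 against 48.9 ± 5.96 CPM (-2.38 ± 0.36, adjusted p = 0.00171, and -2.52 ± 0.36, adjusted p = 0.000660). DNAJB1, a co-chaperone of HSP70, had 11.1 ± 1.26 CPM with KI-ARv-03 against 69.0 ± 15.5 (-2.52 ± 0.37, adjusted p = 0.000757). CCNL2, a cyclin that acts in splicing, was higher: 76.3 ± 21.2 with KB742 and 82.4 ± 34.9 with KI-ARv-03 against 15.1 ± 3.62 CPM (2.25 ± 0.38, adjusted p = 0.00587, and 2.31 ± 0.38, adjusted p = 0.00392). With KB742 the CCNL2 call was lost without DMSO replicate 3 (2.12, adjusted p = 0.0642) and without KB742 replicate 1 (2.05, adjusted p = 0.0890). CLK2, a kinase of splicing factors, was higher with KB742 (2.75, adjusted p = 0.0192) and KI-ARv-03 (2.94, adjusted p = 0.00727). Its call was lost with KB742 without DMSO replicate 1 (1.95) and KB742 replicates 1 and 2 (2.45 and 2.67), and with KI-ARv-03 without DMSO replicate 1 (2.14) and KI-ARv-03 replicate 2 (2.94). The cyclin gene CCNL1 (1.93, adjusted p = 0.0252) and the phosphate transporter gene SLC20A1 (1.65, adjusted p = 0.0347) were higher with KB742. The CCNL1 call was lost without DMSO replicates 1 and 3 (1.60 and 1.94) and KB742 replicates 1, 2 and 3 (1.99, 2.03 and 1.77). That of SLC20A1 was lost without DMSO replicates 1, 2 and 3 (1.69, 1.62 and 1.63) and KB742 replicates 1, 2 and 3 (1.42, 1.72 and 1.80). In all 4 genes were higher and 9 lower with KB742, and 2 higher and 6 lower with KI-ARv-03. The 13 with KB742 went to 6, 8 and 6 without DMSO replicates 1, 2 and 3, and to 3 and 5 without KB742 replicates 1 and 2. Without KB742 replicate 3 it was 9, 2 of them higher. It was 7 on the deposited scaling, 26 with DESeq2 and 0 in a fit of the 2 groups alone. The 8 with KI-ARv-03 went to 5 without DMSO replicate 1, to 5 without KI-ARv-03 replicate 2, to 11 without KI-ARv-03 replicate 3 (5 of them higher) and to 21 with DESeq2. The deposited scaling moved the median of all genes by 0.206 and 0.132, and with KB742 42.9% of the 7 called genes were then higher, against 30.8% of the 13.

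Conversion at 4 h was lower across many more transcripts. TOB2, an antiproliferative adaptor of mRNA deadenylation, had 8.45% ± 3.55 with KB742 and 6.17% ± 0.638 with KI-ARv-03 against 30.9% ± 0.288 with DMSO (adjusted p = 1.45e-05 and 3.34e-06). ONECUT2 had 3.33% ± 0.575 and 3.69% ± 0.653 against 11.1% ± 0.456 (adjusted p = 7.75e-08 and 5.92e-07). CDKN1A, an inhibitor of cell-cycle kinases, had 3.30% ± 0.894 and 2.78% ± 0.549 against 10.7% ± 0.480 (adjusted p = 0.000269 and 0.000107). GAPDH had 0.315% ± 0.0849 and 0.340% ± 0.0878 against 1.17% ± 0.195 (adjusted p = 0.000144 and 0.000314). With KI-ARv-03 the cytokinesis gene RACGAP1 (1.70% ± 0.971 against 0.0730% ± 0.0356), the lysosomal mannosidase gene MANBA (1.63% ± 0.873 (n = 2) against 0% ± 0) and the hexokinase gene HK2 (0.917% ± 0.269 against 0% ± 0) were higher. Without DMSO replicate 3 none of those 3 was (adjusted p = 0.0787, 0.0700 and 0.0726). Nor were MANBA (0.0546) and HK2 (0.0566) without DMSO replicate 2, RACGAP1 without KI-ARv-03 replicate 3 (0.142) or HK2 without KI-ARv-03 replicate 2 (0.0767). In a fit of the 2 groups alone the 3 calls were lost (0.0871, 0.244 and 0.302). With KB742 1326 of 7625 genes were lower and 0 higher in limma (2585 at an unadjusted p under 0.05), and with KI-ARv-03 549 of 7640 were lower and 3 higher (1441 at an unadjusted p under 0.05). The 1326 went to 871 and 727 without DMSO replicates 1 and 3, to 585 and 675 without KB742 replicates 1 and 2 and to 2076 without the 3 libraries that stand apart. The 552 went to 305 without DMSO replicate 3, to 1393, 205 and 270 without KI-ARv-03 replicates 1, 2 and 3, to 332 on a log2 scale and to 1632 without the 3 libraries that stand apart.

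At 8 h the levels, relative to other genes, separated in both directions. No spike-ins were available, so a higher level can also be a smaller fall than that of other genes. TOB2 had 26.9 ± 14.8 CPM with KB742 and 14.3 ± 4.63 with KI-ARv-03 against 166 ± 39.1 with DMSO (-2.72 ± 0.35, adjusted p = 8.91e-05, and -3.47 ± 0.35, adjusted p = 2.75e-06). METTL18 had 5.74 ± 2.81 and 2.39 ± 1.52 against 36.1 ± 14 CPM (-2.47 ± 0.39, adjusted p = 0.000679, and -3.48 ± 0.39, adjusted p = 6.83e-06). DNAJB1 had 13.2 ± 6.53 and 9.62 ± 4.99 against 82.6 ± 31.5 (-2.60 ± 0.37, adjusted p = 0.000198, and -3.0 ± 0.37, adjusted p = 2.38e-05). KLF6 had 36.1 ± 14 and 34.0 ± 10.5 against 211 ± 121 (-2.44 ± 0.35, adjusted p = 0.000252, and -2.50 ± 0.35, adjusted p = 0.000131). RAB3A, a GTPase of vesicle release, differed from DMSO by -2.52 ± 0.37 and -2.89 ± 0.37 (adjusted p = 0.000287 and 3.82e-05). CLK2 was higher: 27.6 ± 10.9 and 24.3 ± 11.9 against 2.58 ± 1.82 CPM (3.05 ± 0.51, adjusted p = 0.00120, and 2.84 ± 0.51, adjusted p = 0.00206). So was CCNL2 (96.8 ± 43.6 and 80.7 ± 49.4 against 14.8 ± 2.46 CPM; 2.56 ± 0.38, adjusted p = 0.000287, and 2.19 ± 0.38, adjusted p = 0.00120). The cell-cycle gene CDC6, which licenses replication origins, had 11.2 ± 3.50 and 15.9 ± 3.15 against 3.07 ± 1.21 CPM (1.60 ± 0.27, adjusted p = 0.00136, and 2.08 ± 0.27, adjusted p = 3.84e-05). At 0 h it had 79.2 ± 8.93 CPM. The cyclin gene CCNA2 had 63.1 ± 30.5 and 76.0 ± 26.3 against 22.2 ± 4.38 CPM (1.35 ± 0.30, adjusted p = 0.0148, and 1.69 ± 0.30, adjusted p = 0.00143) and 184 ± 34.0 at 0 h. Its call with KB742 was lost without DMSO replicate 2 (1.23, adjusted p = 0.0513), KB742 replicate 1 (1.03, adjusted p = 0.117) and KB742 replicate 3 (1.23, adjusted p = 0.0678).

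**Figure D2:**
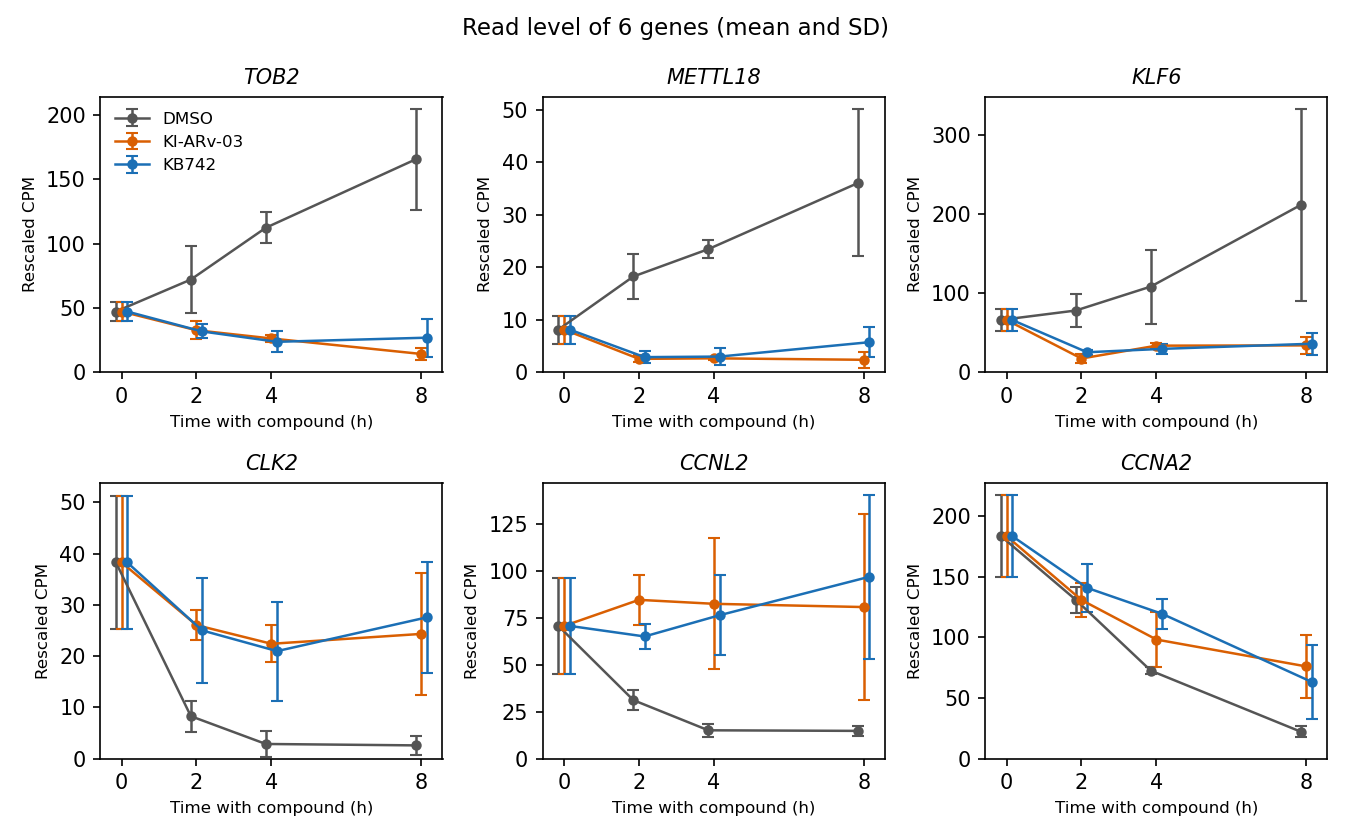
Rescaled CPM (vertical axes, mean ± SD, n = 3) of TOB2, METTL18, KLF6, CLK2, CCNL2 and CCNA2 against hours after compound or DMSO was added (horizontal axes), with all curves starting from the shared 0 h group. At 8 h TOB2, METTL18 and KLF6 are below DMSO with both compounds (26.9 and 14.3 against 166 CPM for TOB2), and CLK2, CCNL2 and CCNA2 are above it.

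Among the genes tested for level at 8 h, 141 were higher and 68 lower with KB742 than with DMSO (1586 at an unadjusted p under 0.05), and 223 were higher and 113 lower with KI-ARv-03 (1947 at an unadjusted p under 0.05). The largest differences with both compounds included the ribosome assembly gene NOL11 (2.55 and 2.44), the chromatin reader gene CDYL2 (2.51 and 2.45) and PIK3CB, a catalytic subunit of phosphoinositide 3-kinase (2.22 and 2.60), all higher. The 209 with KB742 went to 58 without DMSO replicate 3, to 92 and 138 without KB742 replicates 1 and 3, to 398 scaled by library size, to 117 with edgeR and to 0 in a fit of the 2 groups alone. The 68 lower with KB742 were 41 without DMSO replicate 2 and 41 without KB742 replicate 2, and the 113 lower with KI-ARv-03 were 64 without DMSO replicate 2. The 336 with KI-ARv-03 went to 112 without DMSO replicate 3, to 159, 598 and 78 without KI-ARv-03 replicates 1, 2 and 3, and to 3 in a fit of the 2 groups alone. Library-size scaling moved the median of all genes by 0.244 and 0.202 and the deposited scaling by 0.335 and 0.312. Of the genes called 67.5% were higher with KB742 (87.7% and 86.7% in those scalings) and 66.4% with KI-ARv-03 (83.3% and 87.1%).

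By list at 8 h, G2/M genes were higher than with DMSO and ribosomal and respiratory chain genes lower, relative to other genes. The compounds lay between DMSO and 0 h. The median level of G2/M genes was 89.0 CPM at 0 h, 31.1 with DMSO, 63.6 with KB742 and 55.3 with KI-ARv-03. For ribosomal protein genes it was 920, 2713, 1869 and 1900 CPM in that order, and for respiratory chain genes 306, 1007, 751 and 759. Of 22 G2/M genes 3 were higher with KB742 and 4 with KI-ARv-03 (11 and 7 adjusted over the list alone; medians 0.71 and 0.65; camera adjusted p = 1.28e-08 and 3.08e-07), which holds with an estimated correlation (0.00046 and 0.0016). Ribosomal protein genes had medians of -0.57 and -0.48 (-0.31 and -0.26 scaled by library size, -0.20 and -0.14 as deposited; camera adjusted p = 2.28e-11 and 2.4e-07), with adjusted p = 0.0362 for KB742 and adjusted p = 0.159 for KI-ARv-03 with an estimated correlation. Respiratory chain genes had medians of -0.45 and -0.50 (-0.19 and -0.28 scaled by library size, -0.08 and -0.16 as deposited; adjusted p = 2.47e-08 and 1.65e-07), with adjusted p = 0.0362 and 0.0572 with an estimated correlation. Of the 71 ribosomal protein genes limma called 0 (14 and 3 at an unadjusted p under 0.05, 0 adjusted over the list alone), and of the 40 respiratory chain genes 0 with KB742 (11 at an unadjusted p under 0.05) and 1 lower with KI-ARv-03. P-TEFb and elongation genes were called by camera with KB742 (adjusted p = 0.0413, but adjusted p = 0.119 with an estimated correlation), with 2 of 28 higher, and with KI-ARv-03 2 were higher and 3 lower. In this list CTR9, a subunit of the PAF1 complex, had 30.8 ± 9.78 and 34.9 ± 16.1 against 8.82 ± 2.04 CPM (1.67 ± 0.37, adjusted p = 0.0163, and 1.79 ± 0.37, adjusted p = 0.00769). The CTR9 call was lost with KB742 without DMSO replicate 3 (1.53), KB742 replicate 1 (1.51) or KB742 replicate 3 (1.54), and with KI-ARv-03 without its replicate 3 (1.47).

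The remaining lists had few called genes at 8 h, here as higher and lower with KB742, then with KI-ARv-03, without a camera call. Luminal prostate transcription factors had 0 and 0, then 1 and 1 of 15. Immediate early genes had 1 and 2, then 1 and 2 of 23 (adjusted over the list alone 1 and 2, then 2 and 3). Anti-apoptotic genes had 0 of 8 in limma with either compound (2 and 1 at an unadjusted p under 0.05). MYC-activated genes had 1 and 0, then 2 and 0 of 32, p53-activated genes 2 and 2 of 21 with each. DNA repair genes had 0 and 0, then 1 and 0 of 14, and heat shock genes 0 and 1, then 1 and 1 of 17. Integrated stress genes had 0 and 1 of 19 with each, S-phase genes 1 and 0 of 21 with each and histone genes 1 and 0 of 12 with each. Interferon-stimulated genes had 0 and 1, then 0 and 2 of 10, and sterol genes 1 and 0, then 2 and 0 of 19. Limma called 0 of 19 glycolysis and housekeeping genes (0 and 1 at an unadjusted p under 0.05), 0 of 6 NF-kB-activated genes (1 and 2) and 0 of 5 neuroendocrine markers (0 and 0). Adjusted over the list alone, with KB742 the counts were 1 and 0 for DNA repair, 1 and 1 for heat shock, 3 and 1 for integrated stress, 0 and 2 for interferon-stimulated, 3 and 1 for elongation and 3 and 2 for p53-activated genes. With KI-ARv-03 they were 2 and 1 for heat shock, 2 and 2 for integrated stress, 3 and 3 for elongation, 2 and 0 for S-phase and 3 and 0 for sterol genes, and for the other lists they were equal to those over all genes. The median, the mean and the camera direction differed in sign with both compounds for histone, p53-activated and sterol genes. They did so with KB742 for integrated stress and NF-kB-activated genes and neuroendocrine markers, and with KI-ARv-03 for anti-apoptotic genes and luminal factors. At earlier times camera called immediate early genes lower at 2 h (KB742 adjusted p = 0.00181, adjusted p = 0.296 with an estimated correlation; KI-ARv-03 4.03e-07, adjusted p = 0.0212 with an estimated correlation). It did so at 4 h too (0.00414 and 0.000263, adjusted p = 0.399 and 0.151 with an estimated correlation). With KI-ARv-03 at 4 h it also called ribosomal protein genes lower (0.0300, adjusted p = 0.556 with an estimated correlation) and sterol genes higher (0.0335, adjusted p = 0.196 with an estimated correlation).

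Conversion at 8 h was lower with the inhibitors for many transcripts. PPP2R2A, a regulatory subunit of protein phosphatase PP2A, had 3.44% ± 1.60 with KB742 and 3.06% ± 2.00 with KI-ARv-03 against 36.7% ± 7.02 with DMSO (adjusted p = 4.56e-15 and 1.16e-13). ONECUT2 had 2.69% ± 0.180 and 2.25% ± 0.390 against 18.6% ± 2.29 (adjusted p = 4.56e-15 and 2.98e-14). The p53 targets MDM2 and CDKN1A had 0.838% and 0.893% against 7.05% ± 3.44 and 3.64% and 3.39% against 15.9% ± 1.79. GNL3, a nucleolar GTPase that MYC activates, had 4.57% and 4.33% against 26.1% ± 2.48. The mitotic cyclin CCNB1 had 0.849% and 0.828% against 5.6% ± 1.15, and the sterol sensor INSIG1 0.656% and 0.654% against 6.77% ± 1.79. Abundant transcripts went the same way: GAPDH had 0.403% and 0.312% against 1.70% ± 0.533, and RPL35 0.451% and 0.504% against 1.64% ± 0.609. The largest adjusted p among the genes named here was 8.37e-05 with KB742 and 0.000179 with KI-ARv-03, for RPL35.

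**Figure D3:**
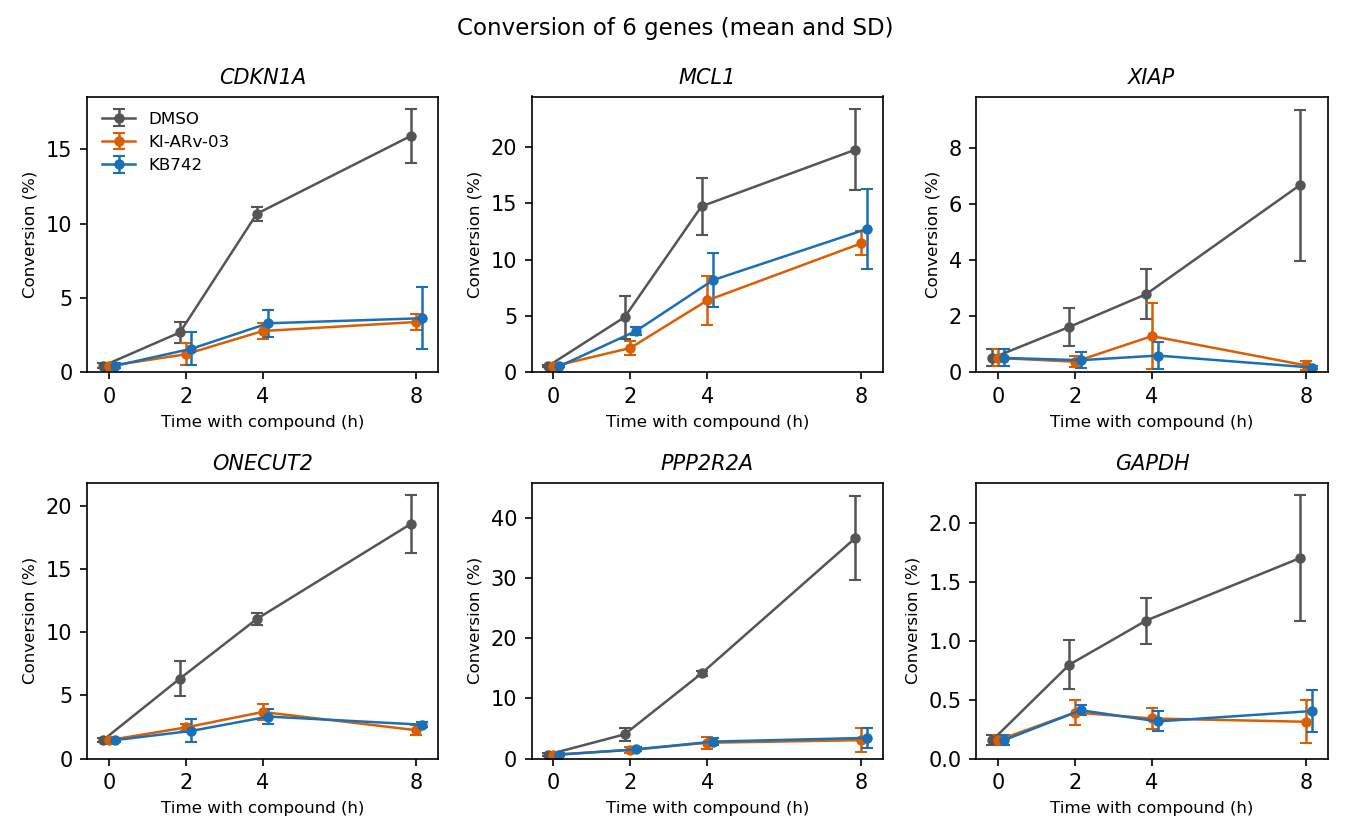
Conversion in percent (vertical axes, mean ± SD) of CDKN1A, MCL1, XIAP, ONECUT2, PPP2R2A and GAPDH against hours after compound or DMSO was added (horizontal axes), with all curves starting from the shared 0 h group. At 8 h PPP2R2A is at 36.7% with DMSO, 3.44% with KB742 and 3.06% with KI-ARv-03.

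With KB742 2173 of 6248 genes had lower conversion than with DMSO at 8 h and 0 higher in limma (2804 at an unadjusted p under 0.05). With KI-ARv-03 2328 of 6313 were lower and 1 higher (2947 at an unadjusted p under 0.05). The 1 was TIMM10, a mitochondrial import gene (2.00% ± 0.229 against 0.203% ± 0.207), which lost its call without DMSO replicate 3 (adjusted p = 0.0587). Without DMSO replicate 2 the totals of 2173 and 2329 went to 1345 and 1476. By list, the counts with lower conversion were 6 of 10 luminal factors with KB742 and 7 of 10 with KI-ARv-03, and 3 of 7 and 4 of 8 immediate early genes. They were 5 of 13 and 6 of 12 elongation genes, 8 of 24 and 10 of 24 MYC-activated genes, 7 of 10 and 5 of 10 p53-activated genes, and 3 of 10 DNA repair genes with each. Heat shock genes had 5 of 12 and 4 of 11, integrated stress genes 6 of 10 with each, and G2/M genes 6 of 14 with each. S-phase genes had 7 of 17 and 9 of 17, histone genes 3 of 11 and 5 of 11, and ribosomal protein genes 19 of 65 and 21 of 66. Respiratory chain genes had 14 of 40 and 15 of 40, glycolysis and housekeeping genes 11 of 18 with each, and interferon-stimulated genes 2 of 4 with each. Sterol genes had 11 of 17 and 11 of 16, and anti-apoptotic genes 3 of 5 with KB742. Adjusted over the list alone, the counts with KB742 were 6 heat shock, 2 histone, 10 integrated stress, 7 luminal, 8 p53-activated, 18 respiratory chain, 15 ribosomal and 13 sterol genes. With KI-ARv-03 they were 7 G2/M, 7 integrated stress, 8 luminal, 12 MYC-activated, 20 ribosomal and 10 S-phase genes, and the other counts were equal. Of 4 neuroendocrine markers limma called 0 with either compound (0 and 1 at an unadjusted p under 0.05). Ribosomal protein genes were lowered less than other genes in the camera test (adjusted p = 0.00157 and 0.0114), but not with an estimated correlation (adjusted p = 0.876 and 0.956 with an estimated correlation). Its direction was upward too, without a call, though median conversion fell, for DNA repair, glycolysis, heat shock, histone, immediate early, MYC-activated and respiratory chain genes and neuroendocrine markers, and with KB742 for G2/M genes. At 2 h camera called luminal factors with KI-ARv-03 (adjusted p = 0.00554, adjusted p = 0.605 with an estimated correlation), and at 4 h with both compounds (0.00648 and 0.0139, adjusted p = 0.974 and 0.847 with an estimated correlation). No camera call on conversion, in any comparison, held with an estimated correlation.

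Of the genes fixed in advance, XIAP, an inhibitor of caspases, had 0.172% ± 0.0466 conversion with KB742 and 0.248% ± 0.170 with KI-ARv-03 at 8 h against 6.67% ± 2.69 with DMSO (adjusted p = 2.66e-08 and 1.65e-07). MCL1 had 12.7% ± 3.55 and 11.4% ± 1.06 (n = 2) against 19.8% ± 3.58 (adjusted p = 0.00985 and 0.00749). It lost both calls without DMSO replicate 3 (adjusted p = 0.0826 and 0.0504) and the call with KB742 without KB742 replicate 2 (adjusted p = 0.0860). On a log2 scale both were lost (adjusted p = 0.149 and 0.112), and in a fit of the 2 groups alone that with KB742 was (adjusted p = 0.0858). At 4 h conversion was lower with KB742 for XIAP (adjusted p = 0.00874) and MCL1 (adjusted p = 0.0136), and with KI-ARv-03 for MCL1 (adjusted p = 0.00276). With KB742 the calls at 4 h were lost without replicate 1 for MCL1 (adjusted p = 0.0993), without replicate 2 for XIAP (0.0556) without DMSO replicate 3 for MCL1 (0.0761) and on a log2 scale for MCL1 (0.0827).

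Of the levels of 9 of these genes limma called 1, that of CDK9 with KI-ARv-03 at 8 h. KLK3, the gene of prostate-specific antigen, had 15.2 ± 9.22 CPM with KB742 and 17.4 ± 2.85 with KI-ARv-03 at 8 h against 28.0 ± 5.67 with DMSO (log2 -1.0 ± 0.46 and -0.65 ± 0.46, adjusted p = 0.318 and 0.477). MYC had 28.2 ± 13.6 CPM at 0 h and was low at 8 h in every group (2.20 ± 1.22 and 0.994 ± 0.403 against 0.543 ± 0.635 CPM; 1.07 ± 0.59 and 0.43 ± 0.59, adjusted p = 0.432 and 0.737). CDK9, the kinase the compounds inhibit, was near the 1 CPM added before the log at 8 h, so its values rest on few reads. It was lower with KI-ARv-03 (0.628 ± 0.556 against 3.46 ± 0.598 CPM, log2 -1.51 ± 0.40, adjusted p = 0.0398) but not called with KB742 (-0.89 ± 0.40, adjusted p = 0.318). That call was lost without DMSO replicates 1, 2 and 3 (-1.45, -1.41 and -1.58) and KI-ARv-03 replicates 1 and 3 (-1.19 and -1.63). It was also lost with replicate blocks (adjusted p = 0.0526), with edgeR (0.0765), without a filter (0.0551) and when scaled by library size (-1.25) or as deposited (-0.76), with adjusted p from 0.0526 to 0.18 over all alternatives that ended it. POLR2A, the largest subunit of RNA polymerase II, was not called (0.89 ± 0.28 and 0.71 ± 0.28, adjusted p = 0.108 and 0.168) but was higher when scaled by library size (1.14, adjusted p = 0.0155, and 0.92, adjusted p = 0.0456). At 2 and 4 h limma called 0 of the 9 with either compound, with log2 differences from -1.27 to 0.47 and -1.23 to 0.54 at 2 h, and -0.95 to 0.51 and -1.31 to 0.47 at 4 h.

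Did KB742 and KI-ARv-03 at these doses differ from each other? The estimated log2 difference at 8 h was 0.96 ± 0.40 for MCL1 (KB742 minus KI-ARv-03, 95% interval 0.14 to 1.79). It was 1.01 ± 0.39 for METTL18 (interval 0.20 to 1.82) and 0.75 ± 0.35 for TOB2 (interval 0.02 to 1.48). For HSPA8, a constitutive HSP70, it was -1.59 ± 0.69 (interval -3.01 to -0.18). At 2 h it was 1.26 ± 0.40 for CDK9 (interval 0.44 to 2.09), or 1.59 with a pseudocount of 0.25 and 0.86 on the deposited scaling. Since these genes were named for an interval that excludes 0, the intervals alone do not show a difference. Other genes had such an interval too. All of these had adjusted p = 1 and so were not called. In leave-one-out fits CDK9 ran from 0.92 to 1.48 and METTL18 from 0.70 to 1.35. HSPA8, MCL1 and TOB2 rest on single libraries. HSPA8 was -0.22 without KB742 replicate 3 and -2.43 without KB742 replicate 2 (-0.87 with DESeq2, -0.84 with edgeR), and MCL1 was 0.48 without KI-ARv-03 replicate 2. TOB2 was 0.48 without KI-ARv-03 replicate 3, 0.38 without KB742 replicate 2 and 1.26 without KB742 replicate 1. Limma called 0 genes for level at 2, 4 and 8 h (232, 157 and 240 at an unadjusted p under 0.05), as did edgeR and DESeq2, and 0 of 8398, 7826 and 6806 for conversion (221, 749 and 178 at an unadjusted p under 0.05). For level these counts are a smaller share of the 11425 genes than the 0.05 that chance gives on average. For conversion that was so at 2 and 8 h but not at 4 h. Without KB742 replicate 1 the count for level at 8 h was 1, and without a filter it was 1 at 2 h and 3 at 8 h. The deposited scaling moved the median of all genes by -0.111 at 2 h. The 95% interval of a gene's log2 difference had a median half-width of 0.865, and lay within ±1 for 37.8%, 38.4% and 36.0% of genes, so a 2-fold difference could not be excluded for the others. For level camera called sterol genes lower with KB742 at 4 h and no list at 2 or 8 h (adjusted p = 0.0362, adjusted p = 0.211 with an estimated correlation).

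Did the effect of a compound change between 2 and 8 h? Conversion of PPP2R2A went from 4.03% ± 1.03 to 36.7% ± 7.02 with DMSO and from 1.53% ± 0.315 to 3.44% ± 1.60 with KB742, and with KI-ARv-03 from 1.44% ± 0.517 to 3.06% ± 2.00. The effect at 8 h differed from that at 2 h (adjusted p = 2.69e-08 for KB742 and 1.49e-08 for KI-ARv-03). The same held for POLE3, a histone-fold subunit of DNA polymerase epsilon, with 18.8% ± 2.05 with DMSO and 3.45% ± 0.413 with KB742 at 8 h (adjusted p = 6.36e-08 and 2.15e-07), though not on a log2 scale of conversion (adjusted p = 0.0549 and 0.0857). XIAP (adjusted p = 0.00534 and 0.00962) differed too, but not with KI-ARv-03 on a log2 scale (adjusted p = 0.0708). Conversion accumulates with DMSO while s4U is present. A constant effect of a compound can therefore widen the gap by 8 h, and these tests do not tell that from a changed effect. For level limma called 1 gene with each compound, CUL1, a ubiquitin ligase scaffold, with KB742 (1.98 ± 0.31, adjusted p = 0.00979) and IST1, an ESCRT-III factor, with KI-ARv-03 (-2.51 ± 0.43, adjusted p = 0.0434). CUL1 went from 77.0 ± 11.3 to 9.85 ± 2.20 CPM with DMSO and from 61.9 ± 8.70 to 33.1 ± 2.19 with KB742. IST1 went from 34.8 ± 4.07 to 69.4 ± 11.8 with DMSO and from 28.7 ± 6.98 to 9.20 ± 2.48 with KI-ARv-03. EdgeR called 1 gene with each and DESeq2 4 and 24. Without DMSO 8 h replicate 2 limma called 7 genes with each compound, all higher, and with KB742 2 without DMSO 8 h replicate 1 or 3. CUL1 lost its call without DMSO 2 h replicate 3 (1.87) and KB742 2 h replicate 1 (1.90), without the 3 libraries that stand apart (adjusted p = 0.0634) and in a fit of the compared groups alone (0.692). IST1 lost it in each of the 12 fits that left out a library of its 4 groups (-2.28 to -2.67, adjusted p = 0.0515 to 0.294). It also lost it with replicate blocks (adjusted p = 0.0722), scaled by library size (-2.24, 0.0839), as deposited (-1.96, 0.382), with summed transcripts (0.0523) and in a fit of the compared groups alone (0.25).

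Library-size scaling moved the median difference of all genes by 0.324 with KB742 and 0.238 with KI-ARv-03, and the deposited scaling by 0.482 and 0.360. For conversion 1 gene differed upwards and 290 of 6165 downwards with KB742, and 1 and 333 of 6213 with KI-ARv-03. Upwards it was MAN2A2, a Golgi mannosidase gene named after its values were seen (adjusted p = 0.00471 and 0.0210). Its conversion went from 2.23% ± 0.523 at 2 h to 0.414% ± 0.513 at 8 h with DMSO, from 0.0720% ± 0.125 to 0.977% ± 0.284 with KB742 and from 0.213% ± 0.369 to 0.622% ± 0.334 with KI-ARv-03. With KI-ARv-03 its call was lost without DMSO 2 h replicate 1 (0.0600), DMSO 8 h replicate 3 (0.0782) and KI-ARv-03 2 h replicates 2 and 3 (0.0590 and 0.0679), with at least 50 reads (0.0559), on a log2 scale (0.0598) and in a fit of the compared groups alone (0.0511). The total of 291 with KB742 went to 175 without DMSO 2 h replicate 1, and to 498, 158 and 159 without DMSO 8 h replicates 1, 2 and 3. It was 186 without KB742 2 h replicate 1 and 180 without KB742 8 h replicate 2. The total of 334 with KI-ARv-03 went to 182 without DMSO 2 h replicate 1, and to 606, 172 and 202 without DMSO 8 h replicates 1, 2 and 3. It was 211 without KI-ARv-03 2 h replicate 3 and 202 without KI-ARv-03 8 h replicate 3. On a log2 scale the totals were 92 and 43, and without the 3 libraries that stand apart 581 and 673.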

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

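The counts over other splits of the libraries were all decided on after the results were seen. The results in this part stand out because the effect of a compound at 8 h differed from its effect at 2 h in a test of that difference. For level limma called CUL1, which scaffolds ubiquitin ligases, with KB742 (1.98 log2, 33.1 ± 2.19 CPM at 8 h against 9.85 ± 2.20 with DMSO). It called IST1, which acts in membrane scission, with KI-ARv-03 (-2.51 log2, 9.20 ± 2.48 CPM at 8 h against 69.4 ± 11.8 with DMSO). These were 1 gene each, against 4 and 24 with DESeq2 and 7 and 7 in limma without DMSO 8 h replicate 2. CUL1 lost its call without DMSO 2 h replicate 3 (1.87), without KB742 2 h replicate 1 (1.90), without the 3 libraries that stand apart (adjusted p = 0.0634) and in a fit of the compared groups alone (0.692). IST1 lost its call in all 12 fits without a library of its groups (-2.28 to -2.67) and with replicate blocks (adjusted p = 0.0722). It did so scaled by library size (0.0839), as deposited (0.382), with summed transcripts (0.0523) and in a fit of the compared groups alone (0.25).

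For conversion 291 genes differed with KB742 and 334 with KI-ARv-03. Because conversion accumulates with DMSO, a constant effect of a compound can also widen such a difference by 8 h. PPP2R2A, a subunit of a protein phosphatase, had an effect at 8 h that lay -30.7 percentage points from its effect at 2 h with KB742 and -31.0 with KI-ARv-03. POLE3, a subunit of DNA polymerase epsilon, lay -13.2 and -12.8 percentage points from it. CCND1, the cyclin of early G1, lay -10.9 percentage points from it with KB742, with 13.6% ± 3.21 conversion with DMSO at 8 h and 1.34% ± 0.313 with KB742. ONECUT2, a transcription factor of the luminal list, lay -12.5 percentage points from it with KI-ARv-03.

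For these differences between times, 100 splits of the 12 libraries of a comparison were counted. With KB742 8 of them gave as many genes for level (highest other split 138 against the real 1) and 9 as many for conversion (1674 against 291). With KI-ARv-03 11 gave as many for level (624 against 1) and 9 as many for conversion (1747 against 334). These splits do not decide on chance, because 8 of the other 99 keep the compound and DMSO libraries apart at 8 h and so carry the compound's whole effect at that time. With KB742 7 of those 8 gave as many genes for level and 8 for conversion, and with KI-ARv-03 8 and 8. Of the 81 splits that mix the libraries at both times, 0 gave as many genes with KB742 for level and for conversion, and with KI-ARv-03 2 and 0.

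For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real and highest other counts of genes for level with KB742 against DMSO were 3 and 0 at 2 h, 13 and 0 at 4 h, and 209 and 0 at 8 h, and with KI-ARv-03 3 and 0, 8 and 0, and 336 and 1. For conversion they were 78 and 0, 1326 and 6, and 2173 and 21 with KB742, and 65 and 0, 552 and 278, and 2329 and 17 with KI-ARv-03. With DMSO against 0 h they were 312 and 0, 2317 and 0, and 5600 and 3 for level, and 699 and 0, 2727 and 1, and 2788 and 2 for conversion. Between the compounds the real count was 0 throughout (limma; 232, 157 and 240 genes for level at an unadjusted p under 0.05, and 0 with edgeR and DESeq2), and all 10 splits gave as many. At 8 h, however, the split of KI-ARv-03 replicates 1 and 3 with KB742 replicate 1 from the rest gave 1928 genes for level against the real 0, which points to a structure of these 6 libraries that does not follow compound. It has both replicates 1 on one side and both replicates 2 on the other, and deviations from the group mean correlated across genes at 0.334 for replicates 1, 0.613 for replicates 2 and -0.206 for replicates 3. With replicate numbers as blocks the count between the compounds stayed at 0. That fit gives a replicate number the same effect in every group, so it cannot decide whether this structure hid a difference.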

How the results depend on the processing

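Alternatives chosen after seeing the data were edgeR on recovered reads, the deposited scaling, a pseudocount of 0.25, the sum of a gene's transcripts, leaving out the 3 libraries that stand apart, the median over genes, and every alternative for conversion. The edgeR test on read counts had been the planned main test, and limma replaced it after the contents of the table were known. Of the genes named in the text none changed direction under any alternative that was run. Of their calls, 775 of 886 held across leave-one-out fits, with library-size scaling 67 of 71, with DESeq2 68 of 70, with edgeR 68 of 71, with at least 50 reads 47 of 49, on a log2 scale of conversion 57 of 67, and in fits of the compared groups alone 72 of 137. Those last fits have fewer libraries to estimate the spread. Of 12 named differences without a call, library-size scaling called 2. For every other change below the cause was not tested.

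Counts of called genes beyond 1.5 times the reported count were as follows. DESeq2 called 7 genes with KI-ARv-03 at 2 h, 26 with KB742 and 21 with KI-ARv-03 at 4 h, 484 with DMSO at 2 h against 0 h, and 4 (KB742) and 24 (KI-ARv-03) for the effect at 8 h against 2 h. EdgeR called 117 with KB742 at 8 h. Library-size scaling called 398 with KB742 at 8 h, and 3 (KB742) and 0 (KI-ARv-03) for the effect at 8 h against 2 h. Without a filter 6 were called with KI-ARv-03 at 2 h, 1 and 3 between the compounds at 2 and 8 h, and 2 for the effect of KI-ARv-03 at 8 h against 2 h. The deposited scaling called 5 and 7 with KB742 at 2 and 4 h, 726 with DMSO at 2 h, and 2 (KB742) and 0 (KI-ARv-03) for 8 h against 2 h. Summed transcripts gave 2 and 0 there, and a pseudocount of 0.25 gave 78 with DMSO at 2 h. A 2-fold minimum kept all 14 counts within 1.5 times.

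In fits of the compared groups alone 0 genes were called for level with KB742 at 2, 4 and 8 h, 0 and 3 with KI-ARv-03 at 2 and 8 h, 167 with DMSO at 2 h, and 0 for the effects at 8 h against 2 h. For conversion these fits called 0 with KB742 and 32 with KI-ARv-03 at 2 h, and 109 for the effect of KB742 at 8 h against 2 h. Replicate numbers as blocks ended the 1 call for the effect of KI-ARv-03 at 8 h against 2 h (0 called), and the calls of CDK9 with KI-ARv-03 at 8 h (adjusted p = 0.0526) and of conversion of TAF2 (0.0516) and THOC6 (0.0605) with DMSO at 4 h. They do not pair the libraries: deviations from the group mean correlated at -0.011 between libraries of the same number (135 pairs, across genes, which are not independent) and 0.006 between others (270 pairs).

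Without the 3 libraries that stand apart (KI-ARv-03 4 h replicate 1, 0 h replicate 3 and KB742 2 h replicate 2), levels gave 0 calls with KB742 and 6 with KI-ARv-03 at 2 h, and 0 for the effect of KB742 at 8 h against 2 h. Conversion then gave 37 with KB742 and 256 with KI-ARv-03 at 2 h, 2076 and 1632 at 4 h, 382 with DMSO at 2 h, and 581 and 673 for 8 h against 2 h. With at least 50 reads conversion gave 105 with KI-ARv-03 at 2 h, 1841 with DMSO at 8 h and 187 for the effect of KB742 at 8 h against 2 h. On a log2 scale it gave 332 with KI-ARv-03 at 4 h, and 92 and 43 for 8 h against 2 h.

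Leaving out 1 library at a time leaves a group of 2 in a fit that pools the spread over all groups. The counts for level then ran from 0 to 3 with each compound at 2 h, 3 to 9 with KB742 and 5 to 11 with KI-ARv-03 at 4 h, and 58 to 216 and 78 to 598 at 8 h. They ran from 0 to 1 between the compounds at 8 h, from 140 to 238 with DMSO at 2 h, and from 0 to 7 for each effect at 8 h against 2 h. For conversion they ran from 11 to 95 with KB742 and 19 to 78 with KI-ARv-03 at 2 h, 585 to 1149 and 205 to 1393 at 4 h, and 1345 to 2114 and 1476 to 2257 at 8 h. They ran from 290 to 651 and 1819 to 2608 with DMSO at 2 and 8 h, and from 158 to 498 (KB742) and 172 to 606 (KI-ARv-03) for 8 h against 2 h.

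With the median over genes in place of mean conversion, the difference from DMSO was -0.215 and -0.445 with KB742 at 2 and 4 h, and -0.186, -0.0227 and -0.651 with KI-ARv-03 at 2, 4 and 8 h. DMSO against 0 h gave 0.257 and 0.527 at 2 and 4 h, and the compounds at 2 h turned direction (-0.0290 for KB742 minus KI-ARv-03). Without ribosomal protein genes the difference was -0.755 with KB742 at 4 h and 0.837 with DMSO at 4 h against 0 h. The difference between the compounds ran from -0.00467 to 0.0716 at 2 h and from -0.388 to 0.0103 at 4 h over leave-one-out values. Of 240 list tests camera called 41, with an estimated correlation 26, fry 59 and with replicate blocks 41.

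The spike-in scaling, the alternatives to it, the spike-in share and the tests of converted reads were not run, since the table holds no spike-ins and no converted reads. Between replicates of a group the chi-square per degree of freedom was 3.99 to 84.1, so the spread exceeded the counting error that depth gives. Simulated 2-fold changes of level were found in 5% of cases and 4-fold changes in 63%, so a level that was not called is not shown to be unchanged.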

Other observations

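The tests of an added background, of a wrong label and of scaling, and the measures of conversion, were decided on after the results were seen. With DMSO at 8 h, RNA of the neuroendocrine granule gene SCG3 was 136 ± 34.1 CPM against 40.2 ± 2.64 at 0 h (1.70 ± 0.27 log2, adjusted p = 1.21e-05). Of 11 neuroendocrine markers 5 were measured, and 4 of them rose (camera adjusted p = 0.0139, 0.0492 with an estimated correlation). Median conversion of the 4 markers with a value was 0.271% with DMSO at 8 h and 0.298% at 0 h. The median change in level was 1.70, or 1.03 scaled by library size and 0.947 as deposited. Of 10 interferon-stimulated genes 6 rose (camera adjusted p = 0.00664, 0.0492 with an estimated correlation), with a median of 1.21, or 0.413 and 0.458 in those scalings. Among them were IRF7, a regulator of interferon genes (3.34 ± 0.62, adjusted p = 0.000105), and IFI35 from 10.4 ± 3.36 to 43.6 ± 1.10 (2.02 ± 0.30, adjusted p = 8.45e-06). HSPA1B, a stress-inducible HSP70, fell with DMSO from 97.0 ± 8.19 to 4.34 ± 4.68 CPM (-4.74 ± 0.68, adjusted p = 4.42e-06). NFKBIA, the inhibitor of NF-kB, fell from 88.9 ± 7.09 to 1.37 ± 1.86 (-5.53 ± 0.51, adjusted p = 9.13e-09).

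Of the 21 p53-activated genes 2 were higher and 2 lower with each compound at 8 h. SESN2, a stress-induced inhibitor of mTORC1, had 1.18 ± 0.920 CPM with KB742 and 0.936 ± 0.596 with KI-ARv-03 at 8 h against 18.2 ± 5.28 with DMSO (-3.19 ± 0.52, adjusted p = 0.000923, and -3.32 ± 0.52, adjusted p = 0.000450). PHLDA3, a repressor of Akt, was lower too (-2.14 ± 0.41, adjusted p = 0.00477, and -2.21 ± 0.41, adjusted p = 0.00272). With KB742 that call was lost without DMSO replicate 3 (-1.98, adjusted p = 0.0530). TNFRSF10B, a death receptor for TRAIL, was higher (14.3 ± 3.40 and 14.8 ± 3.32 against 2.73 ± 2.37 CPM; 2.19 ± 0.38, adjusted p = 0.00154, and 2.24 ± 0.38, adjusted p = 0.00107). In fits of the 2 groups alone SESN2 (adjusted p = 0.0723 and 0.0533), PHLDA3 (0.140 and 0.154) and TNFRSF10B (0.229 and 0.154) lost their calls. BBC3, a pro-apoptotic p53 target, fell with DMSO from 89.3 ± 16.9 to 2.83 ± 1.01 CPM by 8 h (-4.57 ± 0.40, adjusted p = 4.47e-09). Of the 20 markers of basal, stromal, endothelial and immune cells, 2 were measured, too few for a list test. COL1A1, a collagen gene, rose with DMSO from 4.55 ± 3.87 to 16.4 ± 5.84 CPM (1.95 ± 0.51, adjusted p = 0.00287; scaled by library size 1.26, adjusted p = 0.0504). ACTA2, a smooth muscle actin, rose from 3.49 ± 3.24 to 10.5 ± 5.32 (1.69 ± 0.63, adjusted p = 0.0288). The ACTA2 call was lost without 0 h replicate 3 (0.79, adjusted p = 0.293) and without DMSO replicate 3 (1.31, adjusted p = 0.138). It was also lost scaled by library size (adjusted p = 0.178), as deposited (0.75, adjusted p = 0.194), with DESeq2 (0.0639), with edgeR (0.0921) and without a filter (0.0515). In a fit of the 2 groups alone the adjusted p was 0.0790 and without the 3 libraries that stand apart 0.265. COL1A1 conversion at 8 h was 0.615% ± 0.593 (n = 2) with KI-ARv-03 against 9.55% ± 2.47 with DMSO (adjusted p = 0.000342).

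In DMSO the 924 genes with the highest conversion at 2 h (at least 3.56%) fell by 8 h relative to the 4618 less labelled genes. A few genes taking most of the reads was tested by the share of the 10 most abundant genes. That share differed by 2.41 percentage points between 8 h and 0 h, under the 10 set beforehand. Reads taken by a few genes would lower both sets alike, so that share has no bearing on a relative fall. Loss of heavily converted reads before counting stays open, since it predicts a smaller fall with KB742, and the KB742 and DMSO libraries overlapped at 8 h (-1.96, -2.14 and -1.77 against -2.00, -1.62 and -1.55, a difference of -0.23). At 2 and 4 h, for which nothing was set beforehand, KB742 was lower in all libraries, opposite to that prediction (-0.81 to -0.85 against -0.48 to -0.67, and -1.43 to -1.61 against -1.12 to -1.32). Blocked synthesis with KB742 would lower these genes too, so this does not decide it. A response to s4U, to the replaced medium or to time in culture stays open too. The most labelled genes stood at -1.96 with KB742 against 0 h, which blocked synthesis would also give. DMSO itself was not tested apart from these. A library series without s4U, which the design does not have, may tell effects of s4U from those of the medium and of time.

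KI-ARv-03 replicate 1 at 4 h had a mean conversion of 1.18%. By conversion, a DMSO 4 h library under a wrong label is argued against. Its most labelled genes had a median of 3.53%, against 6.78% to 7.31% in the DMSO 4 h libraries and 1.98% to 2.11% in the other KI-ARv-03 libraries. Levels do not tell against it. Relative to less labelled genes, those most labelled with DMSO at 2 h stood at -1.28 log2 from 0 h. That is within the DMSO 4 h range (-1.12 to -1.32) and above the other KI-ARv-03 libraries (-1.48 and -1.42). A library of another time and a mixed sample were not tested. A background added alike to all genes is argued against too. The 661 least labelled genes had 0.705%, against 0.106% to 0.168% with DMSO and 0.056% to 0.063% in the other KI-ARv-03 libraries. The amount over those KI-ARv-03 libraries was 0.642 to 0.649 percentage points for them and 1.41 to 1.54 for the most labelled genes, a difference of 0.834 in the means. A background that differs between genes stays open, as does a biological explanation, and neither was tested.

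The 141 genes higher with KB742 than with DMSO at 8 h include CLK2, CCNL2 and CDC6. Scaling as the cause stays open: 349 genes were higher when scaled by library size alone, but that scaling moves the median of all genes up by 0.244, and no scaling that moves it down was run. A rise above the starting level is argued against for the set: its median stood -0.79 log2 from 0 h with KB742 (-0.61, -1.0 and -0.77 in the 3 libraries), against -2.08 to -2.82 with DMSO and -0.75 to -1.14 with KI-ARv-03. Loss of heavily converted reads from the DMSO libraries stays open. The median conversion at 4 h with DMSO was 1.64% for the 114 of these genes with a value against 1.06% for genes matched on level (percentile 99.8 of 10000 random sets). The genes lower with KB742, however, were at 24.5% against 1.18% (63 of 68 with a value).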
